A study of Mus musculus with 9 samples.

How the data were processed

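Placental tissue of mice at 3 gestation days was measured on 9 arrays, 3 per day, grouped by the day and replicate number in the sample titles. Per the labels' protocols, ribosomal RNA was removed from total RNA, and the rest was amplified by random priming along the transcripts and labelled with Cy3. The deposited scanner files hold intensities per spot, written by Agilent Feature Extraction 11.0.1.1 per the file headers and the submitters' processing notes. The processed intensity is background-subtracted and spatially detrended within each array, per the file headers, which name the mouse build mm9. The authors also deposited a table of processed values on the log2 scale for 60902 probes. Its normalization is not given in the sources used here. Its columns have medians from 6.13 to 6.131, and each of the 9 correlates best with its own array (r of at least 0.9983, against at most 0.9936 with any other), so its scale and direction are those of log2 intensity. Its values gave nearly the same counts of calls as quantile normalization, 5653 higher and 5992 lower against 5655 and 5966 for E14.5 against E7.5, and 8481 and 10322 against 8525 and 10377 for E19.5 against E14.5.

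From the scanner files, control spots were left out, spots of one probe were averaged, and log2 of the processed intensity minus each array's 75th percentile was used. A probe was tested when it was well above background on at least 3 of the 9 arrays and had no spot marked as an outlier, which left out 102 probes and kept 47024. All 9 arrays entered one fit with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 6 residual degrees of freedom and no covariate. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1. The F test over the days used the adjusted p alone. Every adjusted p for a probe comes from limma. Where a probe was not well above background on every array of a day, its fold is a lower bound for the processed signal. The bright day's mean was set against the dim day's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background.

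The files name most probes by a design number alone, and no table used here pairs these numbers with genes. The gene lists, cell type markers and genes fixed before the data were examined therefore could not be tested. Probes named in the text follow the fixed rule as far as it goes without gene names. They are the 3 lincRNA-named probes with the largest rise and the 3 with the largest fall in each comparison, past the threshold, with replicate ranges apart and well above background on all 3 arrays of the higher day. At most 2 numbered probes are named per direction and comparison. Classes of probes were formed from the probe names, and this was chosen after seeing the data. Classes were tested with camera in limma, two-sided, at a preset correlation of 0.01 and with an estimated one, adjusted over the 4 classes within each comparison. The median of each class was also set against 10000 random lists of ASMM10P probes matched on mean level in 40 bins. Tested on 40 lists of 300 probes drawn from the E19.5 against E14.5 changes of 47024 probes, the middle 95% held 35 unmoved lists and none of the lists moved by 0.5, so it runs slightly narrow. Python 3 code used numpy and pandas.

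The fit was tested on simulated data for E14.5 against E7.5 over 47024 probes. Of 50 probes changed by 1.5 log2 units, 38 were called, of 50 changed by 2, 45, and of 50 changed by 4, 50. None of 50 changed by 0.5 was called, which lies under the fold threshold, and 3 unchanged probes were called. The alternatives were quantile, median and other percentile scalings, normexp background correction, the authors' values, other filters, the replicate number as a block, fits of 2 days, array weights, another variance model and leaving out each array. The files lack the mean spot intensity, so normexp used median spot and background intensities, a choice made after seeing the data. The lower bounds on folds hold for the processed signal only. Under normexp, each lincRNA-named or numbered probe given such a bound in the text changed by less than it. Slide as a block was not fitted, since one slide holds E7.5 alone and the fit within the other equals the fit of those 2 days.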

Results

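Placental tissue of mice was collected at 3 gestation days, E7.5, E14.5 and E19.5, counted from a vaginal plug at E0.5. Each day had 3 tissue samples, and each sample was hybridised to its own array, which gave 9 arrays. The arrays carry probes for long non-coding RNAs and other transcripts, and each measured a single dye, Cy3. The deposited files name most probes only by a number of the array's design (names starting with ASMM10P or ASMM10UP) and do not pair these numbers with genes. Caveolin-1 and focal adhesion kinase, the proteins of the study's title, are therefore not reported here. The probes whose names tell what they are form 3 classes of long intergenic non-coding RNA (lincRNA) probes, named human lincRNA, mouse lincRNA and mm9 lincRNA exon. The files also name control probes for the glycolytic enzymes Gapdh and Pgk1.

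Each array held 61500 spots for 60930 probes apart from the controls. On the E7.5 arrays, 73.45%, 73.14% and 74.24% of these spots were well above background, and on the E14.5 arrays 71.52%, 72.53% and 72.93%. On the E19.5 arrays the shares were 71.03%, 63.03% and 63.48%. The 75th percentile of the processed signal was 485.5, 485.1 and 492.1 intensity units at E7.5. It was 462.8, 442.8 and 442.7 units at E14.5, and 287.7, 285.5 and 279.4 units at E19.5. The 1000 brightest spots held from 57.37% to 58.86% of the summed signal at E7.5, from 59.08% to 59.43% at E14.5 and from 64.4% to 65.16% at E19.5. The 3 E7.5 arrays lay on a slide of their own, so slide and day cannot be told apart in comparisons with E7.5. The E14.5 and E19.5 arrays shared the other slide. The number of arrays limits the precision.

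Gestation day separated the 9 arrays. Of 47024 probes tested, 41405 (88.1%) differed among the 3 days in limma's moderated F test at an adjusted p under 0.05. Across probes, which are not independent replicates, arrays of the same day correlated at r from 0.9939 to 0.9951 at E7.5, from 0.9936 to 0.9952 at E14.5 and from 0.9879 to 0.9909 at E19.5. The E14.5 and E7.5 arrays correlated at 0.9124 to 0.9161, and the E19.5 arrays at 0.8116 to 0.8164 with E14.5 and at 0.8032 to 0.8074 with E7.5. The median SD between replicates of one probe was 0.088, 0.089 and 0.114 log2 units at E7.5, E14.5 and E19.5. For the 14785 probes whose mean was at or above the 75th percentile it was 0.053, 0.044 and 0.049. Across the 20 copies of a repeated probe on one array, the median SD was 0.049, 0.046 and 0.043 on these days, about that of bright probes between replicates. Means of those copies varied between arrays of a day by 0.047, 0.017 and 0.029, against spot standard errors of 0.011, 0.01 and 0.01. The labels call the samples independent tissues without saying which animals they came from. The p-values therefore measure the spread between these samples, which may be technical.

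**Figure D1:**
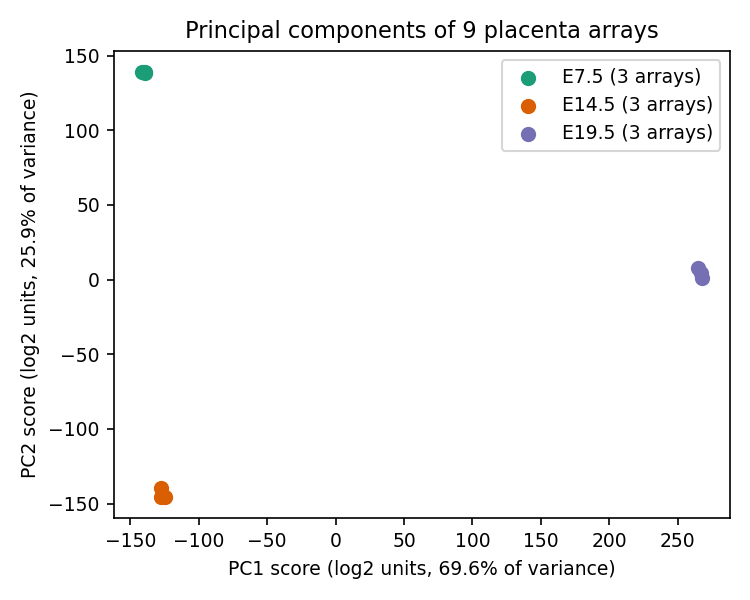
Scores of the 9 arrays on the first 2 principal components of the 47024 tested probes, in log2 units, with 1 point per array and a colour per gestation day. The first component (69.6% of the variance) sets the 3 E19.5 arrays, at 265.14 to 267.74, apart from the other 6, and the second (25.9%) parts E7.5 from E14.5.

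The comparison of E14.5 with E7.5 asked how transcript levels differed between mid and early gestation. At E14.5, 5769 probes were higher and 5929 were lower than at E7.5, with an adjusted p under 0.05 and at least a 2-fold change. The largest changes were rises: 669 probes rose and 236 fell at least 16-fold, and 73 rose and 9 fell at least 256-fold. With dim arrays set to their lowest value above background, 522 rose and 166 fell at least 16-fold, and 63 rose and 5 fell at least 256-fold. The 669 probes held 6.82% ± 0.08 (SD, n = 3) of the summed signal at E14.5 and 0.11% at E7.5. Among the rises, ASMM10P035628 was not well above background on any E7.5 array and rose at least 6370-fold (adjusted p = 1.08e-08). ASMM10P007278, measured on 1 of 3 E7.5 arrays, rose at least 6250-fold. Its fitted log2 change was 13.99 ± 0.591 (SE), and 14.71 without E7.5 replicate 3. ASMM10P024605, not well above background on any E14.5 array, fell at least 195-fold. ASMM10P016843, measured on 1 of 3 E14.5 arrays, fell at least 764-fold. A normexp background correction, which adds an offset of 50 to the signal, gave smaller log2 changes of 10.73, 10.76, -5.85 and -7.59 for these 4 probes in the order named.

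Few lincRNA-named probes passed between E7.5 and E14.5, in both directions. Of 551 tested human lincRNA probes, 41 were higher and 38 lower. Of 344 mouse lincRNA probes, 14 were higher and 20 lower, and of 53 mm9 lincRNA exon probes, 6 were higher and 1 was lower. Of all tested probes, 12.3% were higher and 12.6% lower. In the human, mouse and mm9 classes, 7.44%, 4.07% and 11.32% were higher, and 6.9%, 5.81% and 1.89% lower. The median log2 changes of these classes were 0.05, 0.02 and 0.10, against -0.04 for all tested probes. In limma's camera test these classes did not pass (adjusted p = 0.56, 0.602 and 0.517). Among 10000 lists of ASMM10P probes matched on mean level, the human median lay at percentile 99.23, above the middle 95% of its lists (-0.11 to 0.03). The mouse and mm9 medians, at percentiles 91.1 and 90.39, lay inside the middle 95% of their own lists (-0.13 to 0.05 and -0.28 to 0.17). MM9LINCRNAEXON11712-_P1 rose 13.4-fold (log2 change 3.75 ± 0.078 SE, adjusted p = 6.97e-09), from -4.17 ± 0.15 to -0.42 ± 0.04 (SD, n = 3) relative to the 75th percentile. The probe humanlincRNA0740+_P1 rose 11-fold (adjusted p = 9.52e-06), and MM9LINCRNAEXON11014+_P1, not well above background at E7.5, rose at least 3.17-fold. Among falling lincRNA probes, humanlincRNA1178+_P1 fell at least 15.2-fold and humanlincRNA0848-_P1 at least 15.1-fold. They were measured on 1 and 2 of the 3 E14.5 arrays. The probe mouselincRNA1348+_P1, not well above background at E14.5, fell at least 6.3-fold (adjusted p = 0.000283), and its fitted log2 change of -3.79 was -3.18 without E14.5 replicate 3. Under normexp the 3 falling probes changed by -2.27, -2.27 and -1.39, MM9LINCRNAEXON11712-_P1 by 2.19 and humanlincRNA0740+_P1 by 2.78. MM9LINCRNAEXON11014+_P1 changed by 0.95 and no longer passed the fold threshold.

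The comparison of E19.5 with E14.5, late against mid gestation, was made within one slide. At E19.5, 9774 probes were higher and 9845 lower than at E14.5. That balance depended on scaling, with 7586 higher and 11365 lower under a median shift. With the percentile over probes above background on all 9 arrays the counts were 11799 and 8892. At least 16-fold changes comprised 1112 rises and 1231 falls, and at least 256-fold changes 207 rises and 163 falls. With dim arrays set to their lowest value above background, the 16-fold counts were 966 and 893, and the 256-fold counts 177 and 119. The 1112 probes held 17.06% ± 0.05 (SD, n = 3) of the summed signal at E19.5 and 0.28% at E14.5. The 1231 probes held 10.04% ± 0.04 (SD, n = 3) at E14.5 and 0.1% at E19.5. ASMM10P039685 and ASMM10P037579 were not well above background on any E14.5 array and rose at least 23300-fold and 22900-fold (adjusted p = 5.14e-12 and 8.13e-10). ASMM10P052541 and ASMM10P037430 were not well above background on any E19.5 array and fell at least 10600-fold and 9630-fold (adjusted p = 6.26e-11 and 8.92e-11). Of the lower probes, 2467 were well above background on all 3 E14.5 arrays and on no E19.5 array, while 738 of the higher probes were so on all 3 E19.5 arrays and on no E14.5 array. Fewer spots were above background on the E19.5 arrays of replicates 2 and 3 than on the other 7 arrays.

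**Figure D2:**
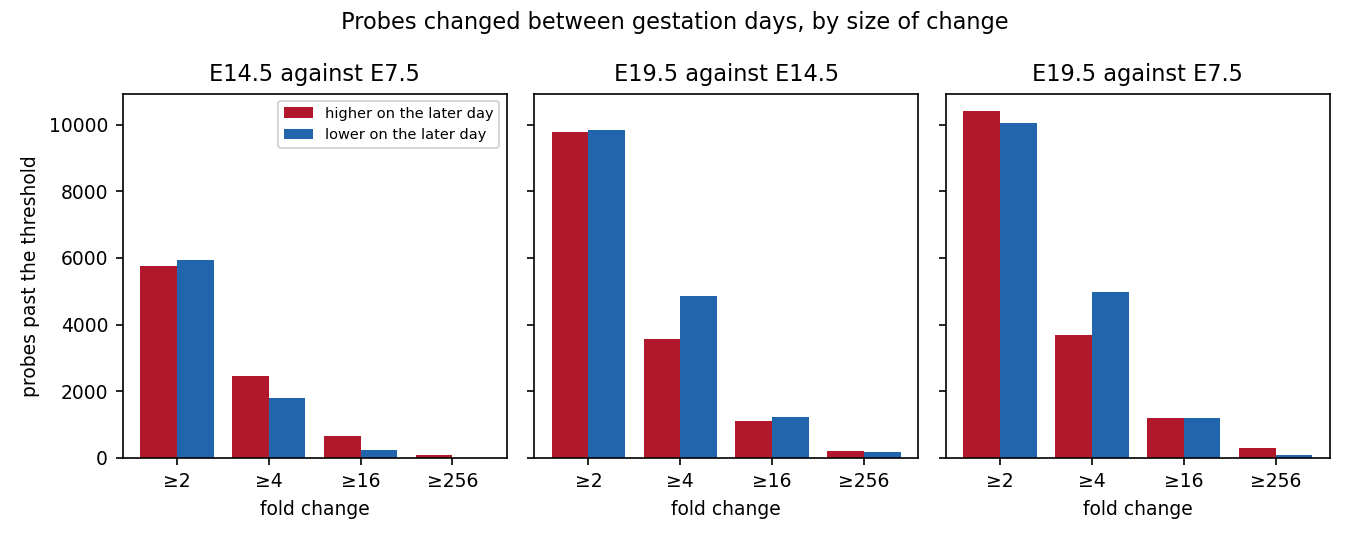
Number of probes past the threshold (vertical axis, from 0) that changed at least 2-, 4-, 16- or 256-fold (horizontal axis), in each of the 3 comparisons, with bars for probes higher and lower on the later day. From E7.5 to E14.5, 669 probes rose and 236 fell at least 16-fold, and from E14.5 to E19.5 the counts were 1112 and 1231.

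Of the 948 lincRNA-named probes, 291 were higher and 30 lower at E19.5 than at E14.5, and the rest did not pass. Of all tested probes, 20.8% were higher and 20.9% lower. Of the human lincRNA probes, 162 were higher, 17 lower and 372 neither. For mouse lincRNA probes the counts were 109, 10 and 225, and for mm9 lincRNA exon probes 20, 3 and 30. In the human, mouse and mm9 classes, 29.4%, 31.69% and 37.74% were higher, and 3.09%, 2.91% and 5.66% lower. The classes thus held more rises and far fewer falls than all tested probes. The median log2 changes were 0.69, 0.69 and 0.85, against 0.23 for all tested probes, and all 3 classes passed camera with a preset correlation of 0.01 (adjusted p = 9.37e-06, 9.37e-06 and 0.00654). With an estimated correlation none did (adjusted p = 0.0528, 0.0653 and 0.0528). Between the same days the difference of 5' minus 3' mouse control probes changed by -1.15 for Pgk1 and -0.45 for Gapdh. Human and rat probe pairs for these genes changed by -1.05 to -1.48. The ASMM10UP probes, whose name the files do not explain, had 85 higher and 67 lower among 436 and did not pass (adjusted p = 0.425). The rises were led by humanlincRNA0111+_P1, 404-fold higher (log2 change 8.66 ± 0.124 SE, adjusted p = 3.54e-10), from -3.49 ± 0.15 to 5.17 ± 0.02 (SD, n = 3). MM9LINCRNAEXON10569-_P1 rose 247-fold and humanlincRNA0324-_P1 88.4-fold, and both were well above background on all 6 arrays. The probe humanlincRNA0740+_P1, which had risen by E14.5, fell by 3.32 on the log2 scale (adjusted p = 7.54e-06). MM9LINCRNAEXON11014+_P1 and mouselincRNA0582-_P1, not well above background at E19.5, fell at least 1.59-fold and 3.55-fold. Under normexp their log2 changes were -0.29 and -0.75, short of the fold threshold, while humanlincRNA0111+_P1 changed by 7.15 and humanlincRNA0740+_P1 by -2.45. The 4 numbered probes named for these days changed by 12.66, 12.59, -11.91 and -11.88 under normexp.

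**Figure D3:**
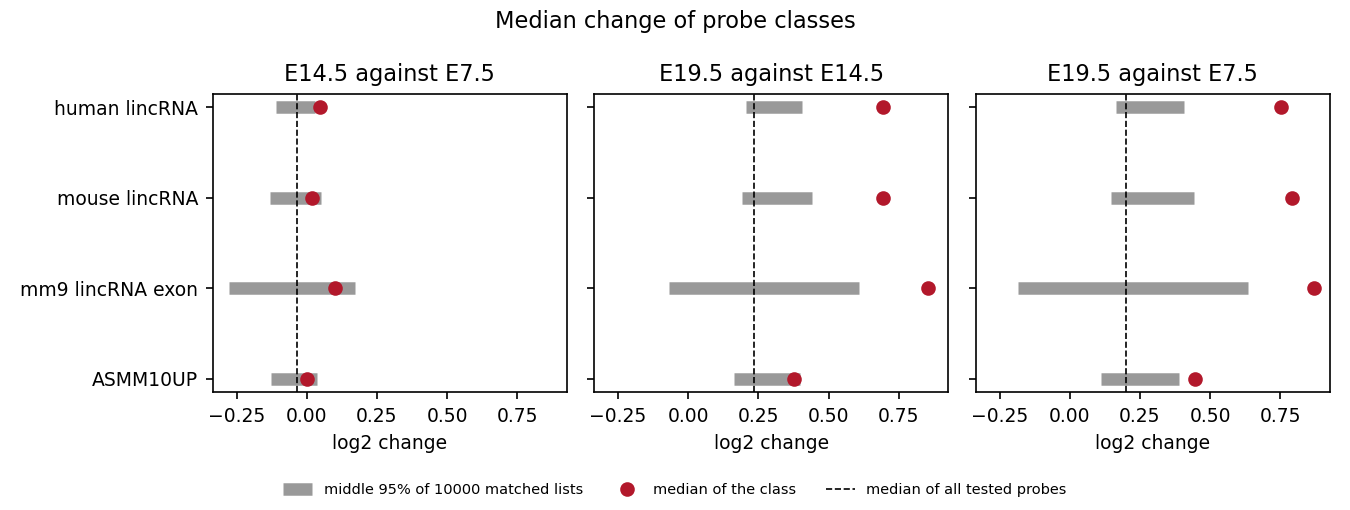
Median log2 change (horizontal axis) of 4 probe classes in each of the 3 comparisons, as points, with grey bars for the middle 95% of medians of 10000 lists of ASMM10P probes matched on mean level and a dashed line at the median of all tested probes. Against E14.5, the human lincRNA median at E19.5 is 0.69 and the bar runs from 0.20 to 0.41.

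Late against early gestation, E19.5 with E7.5, gave 10411 higher and 10047 lower probes. The balance turned with scaling, from 8258 higher and 11370 lower with a median shift to 12153 and 9219 with the percentile over probes above background on all 9 arrays. Of the human lincRNA probes, 191 were higher and 13 lower, of the mouse lincRNA probes 119 and 7, and of the mm9 lincRNA exon probes 22 and 0. These were 34.66%, 34.59% and 41.51% higher, and 2.36%, 2.03% and 0% lower. Of all tested probes, 22.1% were higher and 21.4% lower. Between these days the 5' minus 3' difference of mouse control probes changed by -1.81 for Pgk1 and -0.26 for Gapdh. Human and rat probe pairs for these genes changed by -1.68 to -2.04. Camera passed the 3 classes with the preset correlation (adjusted p = 7.01e-06, 7.01e-06 and 2.29e-05). With an estimated correlation the mouse class missed the threshold (adjusted p = 0.0655), and the human and mm9 classes passed (adjusted p = 0.0456 and 0.0169). The probe humanlincRNA0111+_P1, not well above background at E7.5, rose at least 915-fold. MM9LINCRNAEXON10569-_P1 rose 256-fold, and mouselincRNA1468-_P1, not well above background at E7.5, at least 40.1-fold (adjusted p = 4.57e-06). The probes humanlincRNA0848-_P1, humanlincRNA1178+_P1 and mouselincRNA1348+_P1, not well above background at E19.5, fell at least 10.1-fold, 8.91-fold and 3.52-fold. Under normexp they changed by -2.09, -2.0 and -0.97 on the log2 scale, smaller than these bounds, and the last fell short of the fold threshold. The rises of humanlincRNA0111+_P1 and mouselincRNA1468-_P1 were 7.71 and 3.53 under normexp, also smaller than their bounds. The comparison also spans the 2 slides.

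Across the 2 adjacent comparisons, rises at E14.5 were most often followed by falls. Of the probes higher at E14.5 than at E7.5, 3441 were lower again at E19.5 and 597 rose further. Of those lower at E14.5, 1629 were higher at E19.5 and 1385 fell further. Independent lists of these sizes would share 1208, 1199, 1232 and 1241 probes, but 2 comparisons that share a day are not independent. Both comparisons use the E14.5 arrays, which by itself pushes changes in opposite directions. In 20 simulations of unchanged groups no probe was called in both. With no true change almost no probe can be called, so this sets no benchmark for days that differ. The changes of the 2 comparisons correlated at r = -0.308 across probes, with a covariance of -0.778 against -0.0249 in simulations without effects. Unrelated levels on the 3 days would also give a negative correlation, since both comparisons contain the E14.5 level. These values therefore do not show a rise and fall beyond that. With 3 E14.5 arrays, no split leaves 2 in each part, so some of the excess may come from the shared arrays.

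The mouse Pgk1 control probe for the 5' end was lower on each later day, with replicate ranges apart. Mouse-PGK1_5 stood at 3.62 ± 0.017, 2.36 ± 0.016 and 1.1 ± 0.012 (SD, n = 3) log2 units relative to the 75th percentile at E7.5, E14.5 and E19.5. Its change from E14.5 to E19.5 was -1.46 with a median shift, -1.11 with the percentile over probes above background on all 9 arrays and -1.15 in the authors' values. The 3' probe, Mouse-PGK1_3, differed by -0.60 between E14.5 and E7.5 and by -0.11 between E19.5 and E14.5, where its sign turned with scaling (0.04 with the percentile taken over probes above background on all 9 arrays). Mouse-GAPDH_3 differed by 0.26 between E19.5 and E14.5, and by -0.15 in the authors' values. Mouse-GAPDH_5 differed by -0.20, by -0.05 with that percentile and by -0.61 in the authors' values. Within arrays, the 5' minus 3' difference of Pgk1 changed by -0.67 from E7.5 to E14.5 and by -1.15 from E14.5 to E19.5, and that of Gapdh by 0.19 and -0.45. For the rat Gapdh pair of probes the changes were -0.47 and -1.2. They were -0.88 and -1.05 for the human Gapdh pair, and -0.56 and -1.48 for the human Pgk1 pair. These pairs carry other species' names and target the same genes in mouse RNA, so they are not independent measures of 5' loss. From E7.5 to E19.5 Mouse-GAPDH_5 differed by -0.113, against -1.711 for Rat-GAPDH_5 and -1.635 for Human-GAPDH_5. The rat Pgk1 pair was left out, as its 3' probe was above background on 2 of 3 E14.5 arrays. Control probes were left out of the fit, so these differences were not tested.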

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

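All tests of explanations in this part were chosen after the results were seen. The predictions for the counts over other splits of the arrays were also written after them. Of 54 control probes other than Gapdh and Pgk1, 45 were higher at E19.5 than at E14.5 with replicate ranges apart, 14 of them well above background on all 3 E19.5 arrays. These values are relative to each array's 75th percentile, which was 442.7 to 462.8 units at E14.5 and 279.4 to 287.7 at E19.5. A control probe of constant intensity thus stands higher at E19.5. Of the 14 above background, 4 differed by at least 1 on the log2 scale and drew attention for that reason. The differences were 3.27 for E1A_r60_3, 1.01 for ERCC-00012_90, at least 1.69 for ERCC-00028_121, measured on no E14.5 array, and at least 1.19 for ERCC-00097_63, measured on 2. The negative-control probe 3xSLv1, not well above background on any array, differed by 0.82, a difference between values at the floor. Of the 10 E1A probes, 2 were well above background on all 3 E19.5 arrays, against 2 at E14.5 and 3 at E7.5.

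More probes changed from E14.5 to E19.5 (19619) than from E7.5 to E14.5 (11698), a ratio of 1.68. A slide or scan batch is argued against as the whole cause, since the 2-day fit within one slide called 19440, above the 11887 that leaving out an array gave at most for the comparison across slides. Scaling between arrays is argued against too: the lowest ratio over the scalings was 1.61, and leaving out each array in turn gave ratios from 1.64 to 1.72. Loss of signal from 5' ends can raise a probe only through the scaling. The 75th percentile fell from 442.7 to 462.8 units at E14.5 to 279.4 to 287.7 at E19.5, far short of 16-fold. With dim arrays set to their floor, 966 probes rose at least 16-fold, which argues against this loss for those rises alone. For the smaller rises among the 9774 it was not tested, as that fall raises every probe. For probes that fell, such a loss may contribute and cannot be told apart from a change in the tissue, because the Pgk1 5' minus 3' difference changed by -1.15 and the files do not place probes along transcripts. The difference in gestation day, and with it in tissue content, stays open and untested.

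The 948 lincRNA-named probes had a median log2 change of 0.70 from E14.5 to E19.5, with 291 called higher and 30 lower. Of all tested probes, 20.8% were called higher and 20.9% lower. Low signal level is argued against, as the median of the named probes lay at percentile 100 of 10000 lists matched on level (middle 95% from 0.24 to 0.39). Shifts of whole arrays cannot change the excess of a class median over all tested probes. Under quantile normalization and in the authors' values it was at least 0.43, which argues against scaling as the cause of this excess. The excess by itself does not show whether the intensity of the named probes rose, or held while that of others fell. The 75th percentile was 442.7 to 462.8 units at E14.5 and 279.4 to 287.7 at E19.5. That fall alone raises a probe of constant intensity by about 0.69, the median of the human and mouse classes. The typical probe of these classes thus about held its unscaled intensity, while that of the typical tested probe, at 0.234, fell. The mm9 median was higher, at 0.85. Unscaled intensity is not a transcript level, so a rise in level was not settled. The human class median was 0.49 with a median shift and 0.84 with the percentile over probes above background on all 9 arrays. Normexp shrank the gap, with a median of 0.59 against 0.44 in matched lists, yet left it at percentile 100, which argues against background correction as the whole cause. Random lists take no account of probes that vary together, so their percentiles overstate the certainty of the shift. Camera with an estimated correlation missed the threshold (adjusted p from 0.0528 to 0.0653). The lower quartiles of the human, mouse and mm9 classes were 0.315, 0.266 and 0.339. These lie above the median of 0.234 for all tested probes. The matched lists had medians of 0.312, 0.321 and 0.309. Against these the mouse quartile lay below, the human quartile about level and the mm9 quartile slightly above. The shift thus did not rest on a few probes, but it was small in the lower part of each class. Loss of 5' signal, in whose direction the Gapdh and Pgk1 control probes changed between the same days, and gestation day itself stay open.

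For each pair of days the 6 arrays make only 10 splits, too few for a share under 0.05, and 1 split, the real one, reached the real count. The real counts were 11698, 19619 and 20458 for E14.5 against E7.5, E19.5 against E14.5 and E19.5 against E7.5, and the highest of the other splits was 0 in each. For differences among the 3 days, 1 of 100 splits, the real one, reached 41405, and the highest other gave 23708. Random regrouping of these arrays thus rarely gave as many calls. Regrouping arrays cannot separate day from slide, or from animal if the samples of a day share one.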

How the results depend on the processing

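The normexp fit on median intensities, the fit without the lower slide row and the class tests were chosen after seeing the data. No called result reversed. Normexp gave 3773 higher and 3336 lower probes for E14.5 against E7.5, 5923 and 6155 for E19.5 against E14.5, and 6488 and 6085 for E19.5 against E7.5. The F test, which has no fold threshold, called 45301 probes under normexp, against 41405. The lower counts thus came with smaller folds, not with fewer probes that differed among the days. How much of this the offset of 50 explains was not tested. Keeping only the 34627 probes well above background on all 9 arrays gave 3642 higher and 3638 lower for E14.5 against E7.5, 7369 and 6039 for E19.5 against E14.5, and 7890 and 6035 for E19.5 against E7.5. Fewer probes are tested there, and the share of calls that were higher in the last 2 was 55% and 56.7%, against 49.8% and 50.9%. The ratio of the counts of the 2 adjacent comparisons was then 1.84. Without a fold threshold the counts were 14412 and 15241, 21031 and 15950, and 21164 and 16098. The other counts stayed within 1.5 times: 143 counts did, and 16 did not. Of the named probes' values under alternatives, 632 kept their call and 4, all under normexp, fell short of the fold threshold. Of the class medians 40 moved by more than the replicate SD and 20 did not, and of the Gapdh and Pgk1 differences 29 did and 7 did not. The human lincRNA median for E19.5 against E14.5 was 0.49 with a median shift and 0.84 with the percentile over probes above background on all 9 arrays.

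Leaving out each array in turn gave 5679 to 5792 higher and 5669 to 6100 lower probes for E14.5 against E7.5, 9640 to 9886 and 9764 to 9924 for E19.5 against E14.5, and 10235 to 10740 and 9897 to 10135 for E19.5 against E7.5. Without the 2 E19.5 arrays of the lower slide row, 9889 were higher and 9744 lower than at E14.5, the lone E19.5 array being assumed to vary like the rest. Scaling moved the median change of all probes for E19.5 against E14.5 from 0.03 (median shift) to 0.39 (percentile over probes above background on all 9 arrays), and the share of calls that were higher from 40% to 57%, against 49.8%.

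With the replicate number as a block (replicate block), 5751 probes were higher and 5875 lower for E14.5 against E7.5, 9714 and 9826 for E19.5 against E14.5, and 10377 and 10035 for E19.5 against E7.5. Of these, 11586, 19504 and 20383 were also called without it, and 40916 probes differed among the days. Same-numbered arrays correlated in their deviations at -0.201 to 0.264, so the numbers do not pair the samples, and not every array correlated best with its own number. Not run were slide and scan blocks, normexp on mean intensities, gene list tests and the mean over a gene's probes, for want of those columns, gene names or a slide shared by all days. Signal over background limits the changes of dim probes, most at E19.5.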

Other observations

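The tests of the hypothesis in this part were chosen after the result was seen. Many lincRNA names occur with both a plus and a minus sign, which the files do not explain. Of 547 such human lincRNA names, 103 had both probes well above background on all 3 E7.5 arrays, 247 had 1 and 197 had none. At E19.5 the counts were 81, 230 and 236. Among the 148 human pairs with both probes tested, 69 had 1 probe called between E14.5 and E19.5, 12 had both called in the same direction and 4 in opposite directions. Across these pairs the changes correlated at r = -0.03, and across the 93 mouse lincRNA pairs at -0.05.

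At E7.5, 72% of ASMM10P probes, 41.4% of human lincRNA probes and 44.5% of mouse lincRNA probes were well above background on all 3 arrays. At E19.5 the shares were 61.5%, 35.8% and 39.6%. For mm9 lincRNA exon probes they were 53% and 55.4%.

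Probes with consecutive design numbers changed together more than shuffled ones. Over 36471 consecutive ASMM10P pairs the changes from E14.5 to E19.5 correlated at r = 0.161, above the highest of 1000 shuffled orders, 0.024, and those from E7.5 to E14.5 at 0.149, against 0.018. Position on the array is argued against, since consecutive numbers lay 1.001 times as far apart as shuffled ones. A candidate explanation is that the numbering places probes of related targets next to each other, which needs the gene names to test further.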
